A study of Mus musculus with 4 samples.

How the data were processed

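Native chromatin immunoprecipitation followed by sequencing (native ChIP-seq) was used to map trimethylation of lysine 9 on histone H3 (H3K9me3), a histone mark of heterochromatin, in CD8+ T cells of wild-type C57BL/6 mice. Native ChIP uses chromatin that has not been cross-linked and is cut with micrococcal nuclease. Per the labels' protocols, each immunoprecipitation used 4000000 cells and each library was sequenced to around 100000000 paired-end reads of 150 bases. The labels describe 4 libraries: an H3K9me3 ChIP and an input from naive cells (day 0), and the same pair from cells on day 3 of culture with antibodies to CD3 and CD28 and with interleukin-2. The 2 ChIP libraries, 1 per day, were analysed from the authors' lists of significant islands. The 2 input libraries were not analysed here, so no background measured in input can be set beside the values.

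An island is a run of enriched windows merged into 1 region. Bowtie2, SICER version 1.1 and the mouse genome build mm10 are named in the submitters' processing notes. The significance threshold, the gap size, the treatment of duplicate and multiply mapping reads and the use of the input in calling are not given in the sources used here. Every island border in the deposited lists fell on a multiple of 200 bp, and neighbouring islands were at least 800 bp apart in both lists. Each island carries 1 whole number, deposited by the authors without a column name. It was read here as a raw count of ChIP reads, because it is whole and followed island length across islands (Pearson's r = 0.950 on day 0 and 0.966 on day 3, across islands, which are not independent replicates). These deposited read counts are not scaled for library depth, island length or input. The number of reads mapped and kept in each library is not given in the sources used here, since a list of islands holds only the reads inside them. The reads inside islands summed to 3402787 on day 0 and 10423178 on day 3.

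With 1 ChIP library per day, no test between days was possible and none was made. Differences between days below are differences between these 2 libraries. Intervals are 95% Wilson intervals for shares of islands and exact 95% Poisson intervals for read counts. They cover counting error only, and reads from PCR libraries without molecular identifiers are not independent molecules. The absence of an island means that no region passed the authors' threshold, and does not show that the mark was absent.

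Islands were converted to 1-based coordinates of mm10. Overlap between lists was computed with bedtools 2.31.1 and a minimum of 1 bp. As a reference for placement, each list was shifted circularly within each chromosome 1000 times. The shifts did not leave out sequence where reads cannot be placed. Chromosome lengths were taken as the largest island or gene end on each chromosome, 2722 Mb in all. Gene bodies came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, for 21900 protein-coding genes. That table gives gene starts and ends but neither strand nor exons. The planned promoter, exon and intron classes were therefore not computed, and genic context is given as the share of covered bases inside protein-coding gene bodies. A gene was counted as having an island when at least 1 bp of its body was covered. Covered length is given in kb or as a percentage of the gene body. Bases in overlapping genes count for each of them.

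Before the data were examined, 13 gene lists and 18 gene families defined by symbol were fixed, and all 220 listed symbols were found in the table. The lists cover T cell genes (naive and memory, effector, inhibitory receptor and exhaustion, helper and regulatory), B cell, myeloid, neuronal, liver and muscle, germline, housekeeping, cell cycle and imprinted genes, and the H3K9 methylation machinery. The families are Zfp zinc finger, olfactory receptor, vomeronasal receptor 1 and 2, clustered protocadherin, immunoglobulin V and T cell receptor V segments, Klra and Klrb, major urinary protein, defensin, histone, Prame, Cyp2 and Cyp3, keratin-associated protein, interferon alpha, Skint, Rhox and MHC H2. The number of members with an island was placed among 10000 random lists of the same size, matched on gene length in 10 bins and drawn from protein-coding, lncRNA and V segment genes. The resulting percentile describes these 2 libraries and is not a p-value. Values above 97.5 or below 2.5 are called outside the limits. With 31 lists and families placed on each of 2 days, a few values outside the limits would be expected from random lists too. Members of clustered families are neighbours, so a single island can cover several of them.

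Named genes were fixed by rule. They were the 10 protein-coding genes with the most bases covered on day 3 and not on day 0, the 10 with the most covered on day 0 and not on day 3, and the 5 with the highest covered share on both days (body of at least 5 kb). Predicted genes were left out and at most 2 genes per symbol stem were taken. Of the genes chosen by this rule, 2 are not reported. Members of the T cell lists with an island, and up to 4 members of each other list, were added. Named regions were the 5 islands with the most reads on each day, and the 5 windows of 1 Mb with the highest coverage on each day or the largest difference in each direction. Other genes were named only with a statement that they were chosen after their values were seen, or as the annotation of a named region or of a mitochondrial island.

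The gene list procedure was tested on simulated data, made from the day 0 islands shifted within chromosomes. After islands were added to 100 of 200 randomly chosen genes among 33467, 120 of the 200 carried an island against a mean of 41.9 in random lists (percentile 100.0). Of 200 unselected lists of 50 genes, 6 (3.0%) fell outside the limits. All simulated lists were drawn at random from the genes that also supplied the reference. They were not clustered, so the simulation does not show how the procedure behaves for clustered families. Alternatives were stricter read density, minimum length, merging, other overlap rules, equal list lengths, extended gene bodies and shifted islands. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.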

Results

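H3K9me3 was mapped by native ChIP-seq in naive CD8+ T cells (day 0) and in CD8+ T cells cultured for 3 days under stimulation through CD3 and CD28 with interleukin-2 (day 3). There was 1 ChIP library per day and no replicate, so every difference below is between 2 libraries and has no replicate check. The day 0 list held 19989 islands with 3402787 reads inside them, and the day 3 list held 47553 islands with 10423178 reads. The comparison of the lists shows which regions passed the authors' threshold on each day. The least dense island held 23.6 reads per kb on day 0 and 34.1 on day 3, without correction for depth. The day 0 median was also 34.1 reads per kb, so many day 0 islands were less dense than any day 3 island. An island listed on day 0 only therefore does not by itself show a loss of the mark. Enrichment over background could not be judged from the read counts, as set out in the last paragraph.

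Among the genes of naive and memory T cells, Il7r, Foxo1 and Slamf6 carried an island on day 3 only, and Ets1 carried islands on day 0 only. Il7r, Foxo1 and Slamf6 each lost this difference under an alternative selection of islands given below, and Ets1 kept it. Il7r (mm10 chromosome 15, 9506159 to 9529941), which encodes the alpha chain of the interleukin-7 receptor, had no island on day 0. On day 3, 10.3 kb or 43.5% of its body lay in 1 island (9519601 to 9530800) that held 577 reads. Bach2 (chromosome 4, 32238413 to 32586109), a transcriptional repressor that restrains effector differentiation, went the other way. It was covered over 28.4 kb by 5 islands on day 0 and over 3.2 kb by 1 island on day 3. The day 0 islands in Bach2 with 29.9, 30.0 and 32.4 reads per kb were less dense than any day 3 island (34.1 or more). Those with 34.4 and 34.5 reads per kb were not. Ets1, a transcription factor of lymphocytes, was covered over 7.80 kb on day 0. Bcl2, Satb1, Foxp1 and Myb carried islands on both days, with 8.80, 5.60, 4.80 and 4.80 kb covered on day 0 and 17.4, 18, 11.4 and 8.60 kb on day 3. In all, 6 of the 21 genes had an island on day 0 and 8 on day 3, and 12 had none on either day. These counts stood at percentiles 28.9 and 49.7 of length-matched random lists.

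Of the 24 effector genes, 3 had an island on each day and 20 had none on either. Gzma, which encodes the cytotoxic protease granzyme A, was covered over 6.58 kb or 91.9% of its body on day 0 and had no island on day 3. The transcription factor genes Zeb2 and Prdm1 carried islands on both days, over 30.4 and 8.40 kb on day 0 and 31.7 and 11 kb on day 3. Il2ra, the alpha chain of the interleukin-2 receptor, had a single island on day 3 that covered 1.20 kb. The effector counts stood at percentiles 27.3 on day 0 and 13.6 on day 3 in random lists. With shifted islands they stood at 24.1 and 2.20, so that the day 3 count was below the limits. The drop on day 3 was not particular to effector genes. With shifted islands the day 3 percentiles of the naive and memory, inhibitory, and helper lists were also lower, at 14.25, 12.05 and 6.15.

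Inhibitory receptor and exhaustion genes had an island in 2 of 14 members on day 0 (percentile 12.2) and in 4 on day 3 (percentile 32.9). Tox, a transcription factor of exhausted T cells, was covered over 45.6 kb in 8 islands on day 0 and 87.4 kb in 20 islands on day 3. The inhibitory receptor genes Btla and Cd200r1 had islands on day 3 only, over 13.7 and 13.6 kb. Tigit was covered over 4.6 kb on day 0 and 2.40 kb on day 3. Helper and regulatory T cell genes had an island in 3 of 18 members on day 0 (percentile 75) and in 2 on day 3 (percentile 31.3), with none in common. Cd4 was covered over 10.6 kb (45.0% of its body), Ccr6 over 4.40 kb and Il4 over 4.00 kb (64.5%) on day 0, and none of these 3 had an island on day 3. The day 0 islands in Cd4 and Il4 held 32.7 and 31.5 reads per kb, less than any day 3 island (34.1 or more). That in Ccr6 held 35.2 reads per kb. Il23r, which encodes a receptor subunit used by helper T cells that make interleukin-17, was covered over 20.8 kb and Il21 over 2.40 kb on day 3 only. When the day 3 list was reduced to the 19989 islands with the most reads, the sign of the difference turned for Zeb2, Prdm1, Satb1 and Myb, and Slamf6, Il2ra and Il21 had no island left. With islands of at least the median read density of their list it turned for Tigit, and Il7r, Foxo1, Foxp1, Myb, Cd200r1, Cd4 and Il4 no longer differed. The size of other differences moved as well. The excess on day 3 with the reduced day 3 list was 19 kb in Tox instead of 41.8 kb, 9.60 kb in Il23r instead of 20.8 kb and 1.80 kb in Bcl2 instead of 8.60 kb. With the density limit, the excess in Bcl2 was 1.80 kb, and the difference in Bach2 (day 3 less day 0) was -8.80 kb instead of -25.2 kb.

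**Figure D1:**
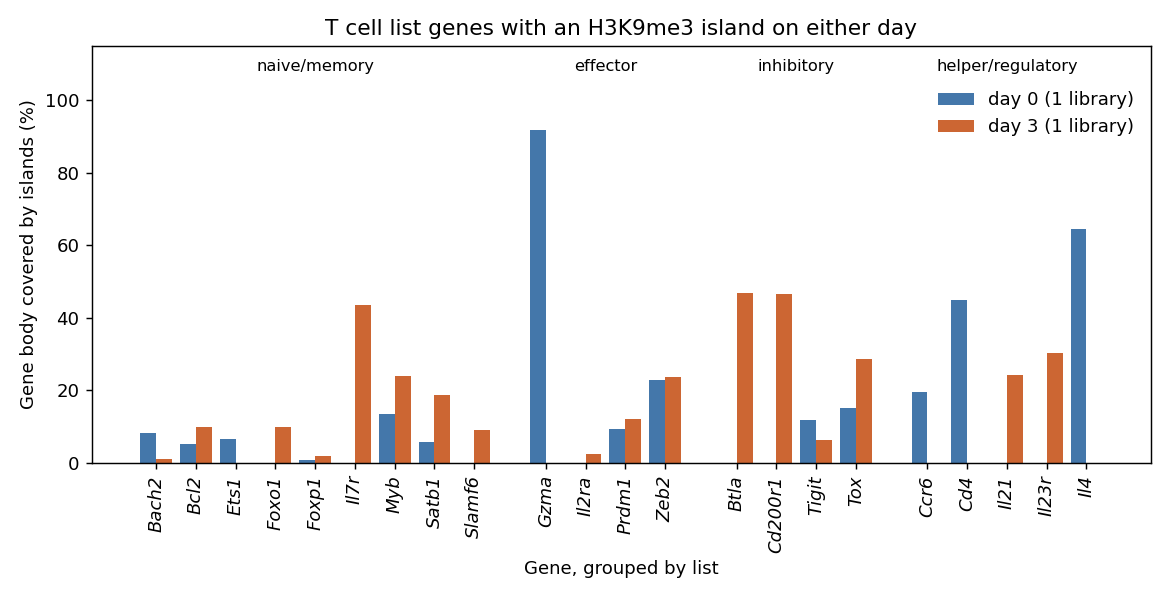
Percentage of each gene body (y axis) covered by islands on day 0 (blue) and day 3 (orange), for each T cell list gene (x axis) with an island on either day, with 1 library per day and no error bars. Gzma, Cd4 and Il4 show islands on day 0 alone, and Il7r, Btla and Cd200r1 on day 3 alone.

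**Figure D2:**
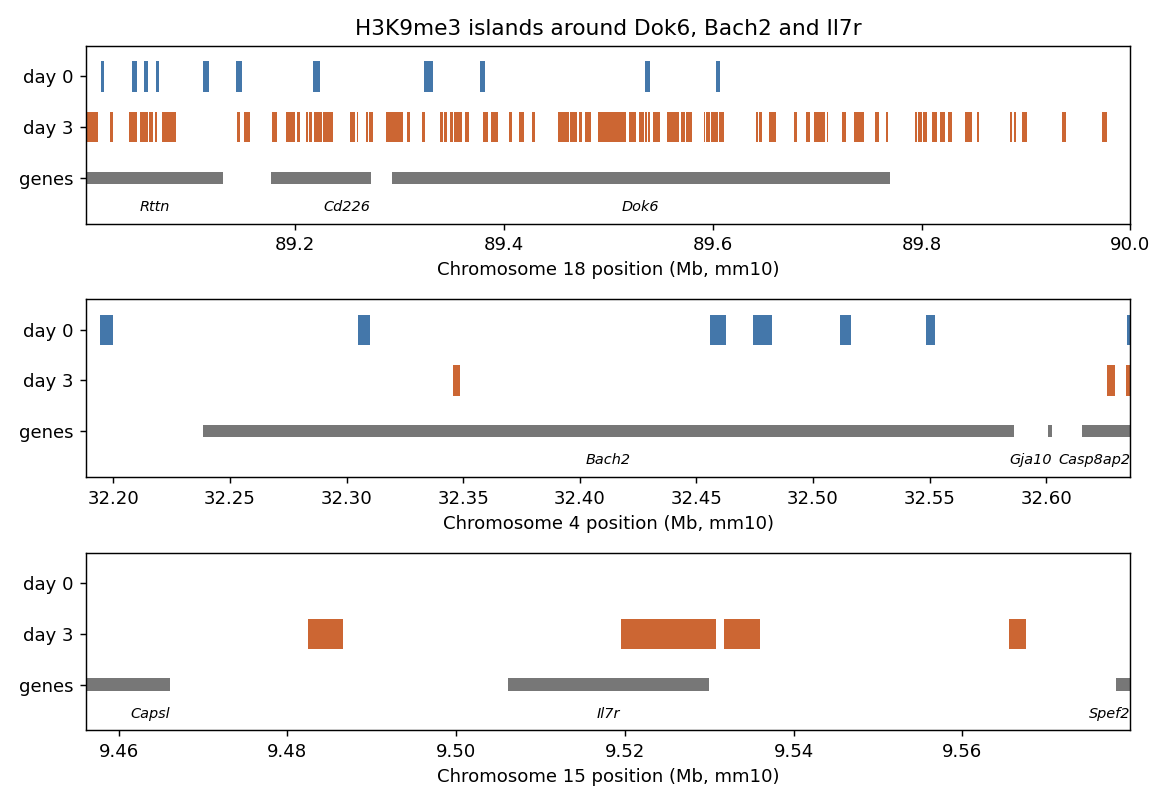
Islands of day 0 (blue) and day 3 (orange) above protein-coding gene bodies (grey), drawn to scale along each chromosome in Mb of mm10, for examples chosen after the values were seen. Dok6 was covered by 4 islands on day 0 and 41 on day 3, Bach2 by 5 and 1, and Il7r by none on day 0 and 1 on day 3.

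The protein-coding genes with the most bases covered on day 3 and not on day 0, summed over separate islands, were very long. Dlg2 had 289.4 kb of this kind, Magi2 284.0 kb, Lrp1b 271.4 kb, Pde4d 257.2 kb, Cntnap2 255.6 kb, Immp2l 250.2 kb, Inpp4b 249.8 kb, Nrxn3 243.4 kb, Zbtb20 231.8 kb and Ccser1 229.0 kb. Dlg2, Magi2, Lrp1b, Cntnap2 and Nrxn3 are best known from neurons, where they encode synaptic scaffold, receptor and adhesion proteins. Inpp4b (chromosome 8, 81342266 to 82134312), a phosphoinositide phosphatase gene, was covered over 4.04% of its body on day 0 and 32.8% on day 3. Zbtb20, a transcriptional repressor gene, was covered over 8.38% and 34.1%. The net excess of day 3 in these genes depended on the islands counted. It was 205.6 kb in Dlg2 with all islands, 56.6 kb with equal list lengths and 74.2 kb with the density limit, and in Lrp1b it was 244.8, 108.8 and 67.4 kb. The genes with the most bases covered on day 0 and not on day 3 were again long, led by Pde4d with 93.8 kb, Sox6 with 88.8 kb, Celf2 with 84.6 kb, Dlg2 with 83.8 kb and Cntnap2 with 73.6 kb. They were followed by Sox5 with 73.2 kb, Magi2 with 71.4 kb, Fbxl17 with 69.0 kb and Thsd7b with 68.4 kb. Pde4d, Dlg2, Cntnap2 and Magi2 stood in both groups, since their day 0 and day 3 islands covered different parts of the gene. Genes with less coverage on day 3 in net terms, chosen after their values were seen, included Kif26b (48.4 kb on day 0 and 8.80 kb on day 3), Garem1 (38.7 and 3.40 kb) and Magi1 (31.6 kb and none). Among the genes with the highest coverage on both days were Tcf24 (87.5% of its body on day 0 and 66.5% on day 3), Tmem74bos (65.6% and 77.4%), Chil6 (61.6% and 67.1%) and the sperm hyaluronidase gene Spam1 (61.0% and 62.9%). With the density limit Chil6 had no day 0 coverage and Tmem74bos no day 3 coverage, and with equal list lengths Spam1 had no day 3 coverage.

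Germline genes had an island in 6 of 12 members on day 0 and 8 on day 3, at percentiles 96.6 and 99.5. With shifted islands the percentiles were 96.8 and 95.7, inside the limits on both days. The RNA helicase gene Ddx4 was covered over 53.0% of its body on day 0 and 63.0% on day 3, the sperm ATP/ADP carrier gene Slc25a31 over 52.3% and 73.7%, and the Piwi gene Piwil2 over 10.9% and 15.5%. Sycp1, a gene of the meiotic synaptonemal complex, was covered over 12.1% and 33.4%. Neuronal genes had an island in 16 of 18 members on each day (percentiles 98.6 and 96.0). Their bodies had a median length of 967 kb, and with shifted islands the percentiles were 60.0 and 39.1. B cell genes had an island in 3 of 12 members on each day (percentiles 62.1 and 46.2), among them Ebf1 with 29.0 and 41.8 kb and Cr2 with 12.6 and 13.2 kb covered. Myeloid genes had an island in 2 of 14 on each day (percentiles 55.8 and 43.9), which were Csf1r and Siglech on day 0 and Adgre1 and S100a9 on day 3. Liver and muscle genes had an island in 4 of 17 on each day (percentiles 90.2 and 81.4). The cardiac actin gene Actc1 was covered on day 0 only (87.9% of its body), and the fibrinogen gene Fgb on day 3 only (66.5%).

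Genes of the H3K9 methylation machinery had an island in 8 of 15 members on day 0 and 7 on day 3 (percentiles 96.2 and 74.4). With shifted islands the percentiles were 99.05 and 59.6, which puts the day 0 count above the limits. The demethylase gene Kdm4c was covered over 8.80 kb on day 0 and 43.8 kb on day 3, and the methyltransferase gene Ehmt1 over 7.20 and 18 kb. Cbx5, which encodes the heterochromatin protein HP1 alpha, was covered over 13.1 kb on day 0 only. Atf7ip, a cofactor of the methyltransferase Setdb1, was covered over 6.3% of its body on day 0 and 20.6% on day 3. Imprinted genes had an island in 9 of 21 members on day 0 and 6 on day 3 (percentiles 87.6 and 14.6). Kcnq1 was covered over 50.8 and 33.0 kb, Kcnq1ot1, which lies within it, over 23.7 and 27.3 kb, and Grb10 over 16.2 and 22.2 kb. The imprinted genes with an island on day 0 only, named after their values were seen, were Meg3 (3.80 kb), Igf2r (3.40 kb) and Impact (2.80 kb). Housekeeping genes had an island in 1 of 18 members on day 0 (Sdha) and 3 on day 3 (Sdha, Ywhaz and Tbp), at percentiles 26.6 and 63.6. Cell cycle genes had an island in 1 of 16 on day 0 (Bub1) and 2 on day 3 (Bub1 and Ccna2), at percentiles 19.4 and 27.9. Bub1, a spindle checkpoint kinase gene, was covered over 1.80 kb on day 0 and 19 kb on day 3.

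Olfactory receptor genes, a family of short genes that sit in large clusters, had an island in 60 of 1106 members on day 0 and 175 on day 3. The means in random lists were 36.6 and 69.4, and both counts were at percentile 100.0. With shifted islands the means were higher, at 63.1 and 119.5. The day 0 count was then at percentile 42.6 and the day 3 count at 98.5. Zfp zinc finger genes, many of which encode repressors that recruit H3K9 methylation, had an island in 70 of 394 members on day 0 and 120 on day 3. Their percentiles were 6.03 and 98.8, and 28 on day 3 with shifted islands. Zfp407 was covered over 42.8 kb on day 0 and 114.0 kb on day 3, and Zfp280d over 23.6 and 58.4 kb. Vomeronasal receptor 2 genes had an island in 7 of 123 members on day 0, fewer than in any random list (mean 25.6), and in 30 on day 3 (percentile 23.1). Vomeronasal receptor 1 genes had one in 5 and 8 of 230 members (percentiles 19.7 and 3.40). Clustered protocadherin genes, whose bodies overlap one another, had an island in 13 of 57 on day 0 and 34 on day 3. Their percentiles were 0.050 and 99.9 in random lists and 15.8 and 44.2 with shifted islands.

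Across all 21900 protein-coding genes, 4962 had an island on day 0 and 5937 on day 3. An island, not always in the same place, was present on both days in 3485 genes, on day 0 alone in 1477 and on day 3 alone in 2452. This order depended on which islands were counted. With the day 3 list reduced to the 19989 islands with the most reads, which are mostly the longer ones, day 0 alone held 2328 genes and day 3 alone 1283. Of the bases covered on autosomes, 50.2% lay in protein-coding gene bodies on day 0 and 47.1% on day 3, while gene bodies made up 40% of the autosomes. The autosomes were counted up to their largest island or gene end, with no correction for sequence where reads cannot be placed.

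Islands covered 100.5 Mb on day 0 and 198.6 Mb on day 3, which is 1.98 times as much, with 2.38 times as many islands. The median island length was 4800 bp on day 0 (quartiles 3800 and 5800) and 3600 bp on day 3 (quartiles 2800 and 5000). The median read density was 34.1 reads per kb on day 0 (quartiles 31.9 and 36.7) and 52.9 on day 3 (quartiles 49.0 and 57.5). In 7306 overlapping pairs of islands, day 3 had a median of 1.57 times the read density of day 0 (quartiles 1.43 and 1.72), without correction for depth. The median densities in these pairs, 34.2 and 53.5 reads per kb, were close to those of all islands. The ratio is therefore not particular to shared regions. A day 3 island overlapped 6722 of the day 0 islands, or 33.6% (95% Wilson interval 33.0 to 34.3), and 13267 had no overlap. Circular shifts gave a mean of 16.8% and at most 18.3%. Shifts within 50 to 500 kb, chosen after seeing the data, gave a mean of 20.8% and at most 22.0%. In the other direction, 7065 of the day 3 islands (14.9%, interval 14.5 to 15.2) overlapped a day 0 island. Circular shifts gave a mean of 7.39% and at most 8.04% here, and the shorter shifts 9.23% and at most 9.88%. When an overlap of at least 50% of the island was asked for, the observed shares were 20.9% and 10.04%.

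In the lists as deposited, every autosome had more covered sequence on day 3. On day 0 the share ran from 2.79% of chromosome 8 to 5.13% of chromosome 13, and on day 3 from 5.22% of chromosome 7 to 10.1% of chromosome 2. The ratio of day 3 to day 0 was highest on chromosomes 15 (2.69) and 16 (2.51) and lowest on chromosome 11 (1.44). Chromosome X held 1 island on day 0 and 3 on day 3. At the density of islands on the autosomes, 1386 and 3298 would have been listed there. The day 0 island on X (169982201 to 169983200, 211 reads, interval 183 to 241) lay in Mid1, and 1 of the day 3 islands lay in Dach2. Both genes were named after their values were seen. Chromosome Y held 2 islands on each day.

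**Figure D3:**
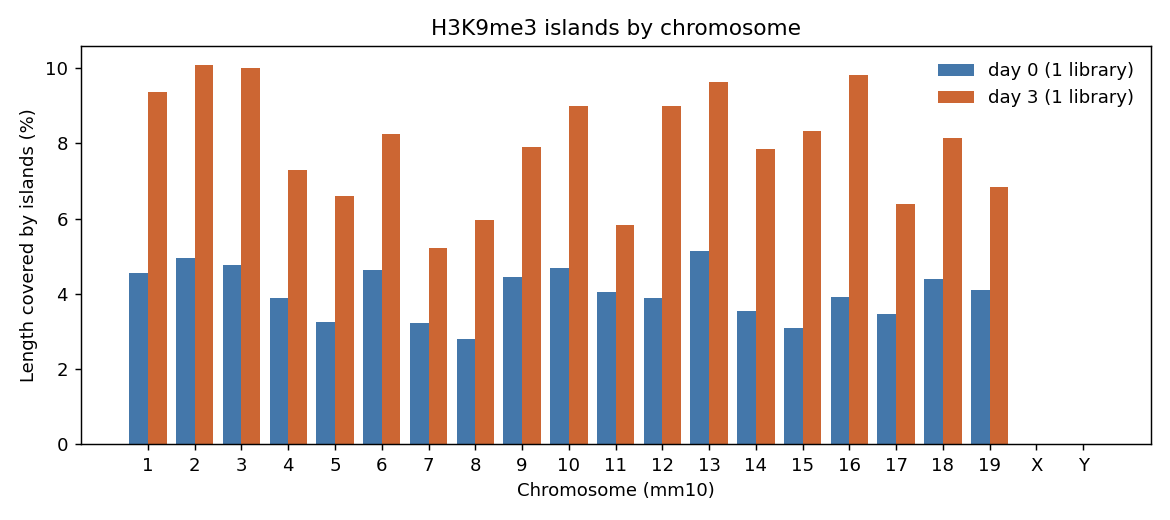
Percentage of each mm10 chromosome (x axis) covered by islands (y axis) on day 0 (blue) and day 3 (orange), with 1 library per day and no error bars. All autosomes lie between 2.79% and 10.1%, and X and Y are close to 0.

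The 1 Mb windows with the highest coverage on day 3 lay on chromosome 18 from 89000001 (38.5%, against 5.40% on day 0), which holds the activating receptor gene Cd226, Dok6 and part of Rttn, and on chromosome 1 from 95000001 (38.5% against 5.84%), which holds St8sia4. Next came chromosome 13 from 89000001 with Edil3 and Vcan (35.6% against 12.4%) and chromosome 2 from 44000001 with Arhgap15 (35.2% against 10.8%). Chromosome 3 from 60000001, with Mbnl1, was among the highest on both days (34.2% on day 3 and 18.6% on day 0). The highest on day 0 was chromosome 2 from 62000001 with Dpp4, Gcg and Ifih1 (19.5%, and 32.5% on day 3). Others high on day 0 were chromosome 1 from 69000001 with Erbb4 and Ikzf2 (17.5%), chromosome 2 from 79000001 with the integrin gene Itga4 (17.4%) and chromosome 13 from 101000001 with Pik3r1 (15.9%). Windows on chromosome 15 from 50000001 with Trps1 (4.36% and 33.2%), chromosome 16 from 51000001 (2.62% and 27.8%) and chromosome 12 from 93000001 (1.06% and 25.6%) completed the 5 with the largest excess on day 3. The largest excess on day 0 was on chromosome 4 from 117000001, with Rnf220 and Kif2c (10.1% on day 0 and 2.24% on day 3). It was followed by chromosome 8 from 91000001 with Fto and Rpgrip1l (11% and 3.82%), chromosome 6 from 94000001 with Magi1 (8.92% and 3.00%), chromosome 12 from 80000001 with Zfp36l1 (9.52% and 3.78%) and chromosome 6 from 55000001 with Aqp1 (8.56% and 3.14%). Over 2433 autosomal windows, 1821 were covered more on day 3 and 533 more on day 0. Coverage on the 2 days correlated across windows (Pearson's r = 0.585, Spearman's rho = 0.572), which are not independent replicates.

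**Figure D4:**
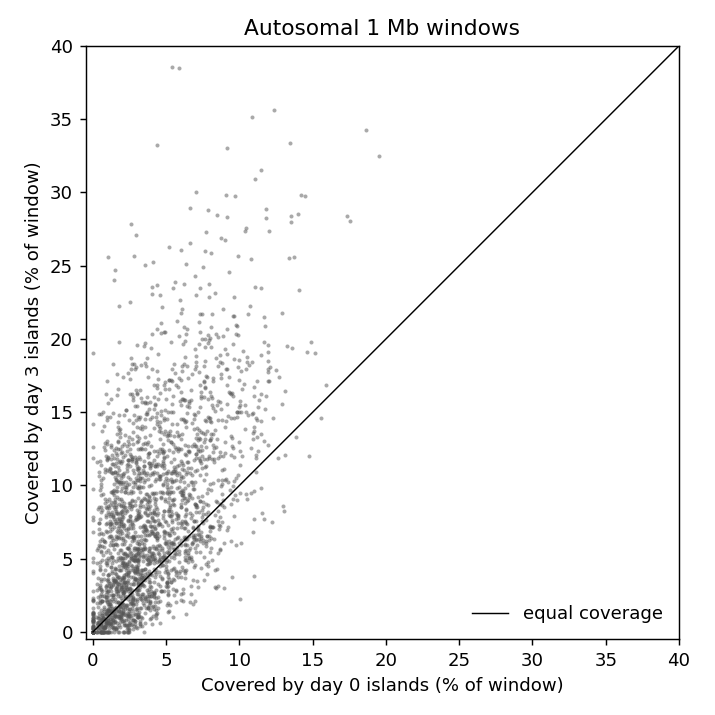
Coverage of autosomal 1 Mb windows by islands of day 0 (x axis) and day 3 (y axis), in percent of the window, with 1 point per window. The line marks equal coverage, and 1821 of the 2433 points lie above it.

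The island with the most reads on day 0 was on chromosome Y (90797601 to 90813000, 1479 reads, interval 1405 to 1556), and 14.2 kb of its 15.4 kb were also covered on day 3. It was followed by islands on chromosome 17 from 13540401 (823 reads), chromosome 16 from 13453801 (745 reads), chromosome 15 from 66604001 in Phf20l1 (669 reads) and chromosome 7 from 100335001 in Ppme1 (645 reads). On day 3 the most reads lay at the start of the mitochondrial genome (3338 reads), then on chromosome 9 from 75133201 in Myo5a (1838 reads) and from 72335001 in Zfp280d (1771 reads). Islands on chromosome 1 from 160541201 in Rabgap1l (1682 reads) and on chromosome 19 from 29731201 (1570 reads) came next.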

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

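Islands were listed on the mitochondrial genome, which carries no histones and was outside the comparisons of chromosomes and windows. Its genes under islands are within the counts of protein-coding genes with an island. The mitochondrial islands held 567 reads on day 0 (95% Poisson interval 521 to 616) and 5168 reads on day 3 (5028 to 5311). They are given here as a signal outside those comparisons. A listed island always holds reads, so no test lies behind them. The islands overlapped ND1, ND2, ND4 and ND5, and on day 3 also ND6 and CYTB. Their read density was 2.79 times that of autosomal islands on day 0 and 11.2 times on day 3, and whether input libraries show the same was not analysed here.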

How the results depend on the processing

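No paired analysis was possible because each day has 1 ChIP library, and no replicate could be left out. The promoter alternatives (within 1 or 2 kb of a transcription start) were not run, since the gene table used gives no strand. Shifts within 50 to 500 kb, the restriction to autosomal genes and the 100 length bins were chosen after seeing the data. Of 59 alternative values of the main results, 35 stayed within 1.5 times the main count or within the interval of the main share, and 24 did not. With islands of at least the median read density of their list, 10001 islands (42.6 Mb) were left on day 0 and 23797 (85.2 Mb) on day 3, by construction. The share of overlapping islands was then 20.7% on day 0 and 9.03% on day 3, and 3170 genes had an island on day 0 and 2011 on both days. Overlap of at least 50% of the island gave 20.9% and 10.04%, and reciprocal overlap of at least 50% gave 16.5% and 6.92%. With as many day 3 as day 0 islands, the shares were 20.6% and 20.3%, 3917 genes had an island on day 3, 2328 on day 0 only and 1283 on day 3 only. For the full lists and the 1 bp rule, the shares expected from shifts within 50 to 500 kb were 20.8% and 9.23%. No expected shares were computed for the other overlap rules, the density limit or equal list lengths. Chromosome X kept 0 islands of at least 2 kb on day 0. Of the gene lists, 2 lay above the limits on day 0 in the main comparison and 1 each with shifted islands, autosomal genes or 100 length bins; on day 3 there were 4, and 1 with shifted islands. On day 0 the neuronal and olfactory receptor lists were above the limits in the main comparison. With shifted islands neither was, and the H3K9 methylation machinery was instead. With autosomal genes or 100 length bins only the olfactory receptors were. On day 3 the olfactory receptors stayed above the limits with shifted islands, and the germline, Zfp and protocadherin lists did not. Below the limits, the effector T cell genes entered and the Rhox family left on day 3 with shifted islands, and the protocadherins left on day 0. With 100 length bins the histone genes left and the Skint family entered on day 0. With autosomal genes the Skint family entered on day 0, and the vomeronasal receptor 1 family entered on day 3, when Rhox could not be compared. Among 43 genes fixed by the naming rule or the T cell lists, the difference in covered kb moved by over 1.5 times without a change of sign, or became 0, in 22 with equal list lengths and 26 with the density limit. The sign of the difference (kb covered on day 3 less day 0) turned for 7 with equal list lengths, to -12.8 for Thsd7b, -10.9 for Zeb2, -6.01 for Spam1, -15.6 for Sox6, -0.20 for Myb, -3.00 for Prdm1 and -4.39 for Satb1. With the density limit it turned for 3, to -4.44 for Tmem74bos, -18.6 for Sox6 and 2.40 for Tigit. The cause of these changes was not tested. The reduced day 3 list kept the islands with the most reads, so list length and this selection were not separated. The mapped depth of each library is not given in the sources used here, which limits every comparison of read counts.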

Other observations

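The tests of a chromosome X left out of the processing and of a deeper day 3 library, and the shifts within 50 to 500 kb, were chosen only after the results were seen. Further gene families were placed among random lists. Cyp2 and Cyp3 genes, cytochrome P450 enzymes of drug and steroid metabolism, had an island in 2 of 54 members on day 0, fewer than in any random list (mean 12.1), and in 14 on day 3 (percentile 34.2). Cyp3a13 was covered over 23.3% of its body on day 0 and 21.4% on day 3, and Cyp2c29 over 13.4 kb on day 3 only. Histone genes had an island in 0 of 103 members on day 0 and 1 on day 3 (H2bc6), at percentiles 1.41 and 0.51. Prame genes had an island in 2 of 48 on day 0 (Pramel1 and Pramel12) and 0 on day 3 (percentiles 4.38 and 0.010). Rhox genes, all 33 of them on chromosome X, had none on either day (percentiles 4.26 and 1.65). With shifted islands, which stay on their chromosome, the Rhox percentiles were 49.95 and 49.45, so the low values follow from the near-empty X. Skint genes had an island in 2 of 11 members on day 0 and 8 on day 3 (percentiles 3.25 and 93.7), with Skint10 covered over 12.6 kb on day 3 only.

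T cell receptor V segments had an island in 4 of 148 members on day 0 and 7 on day 3 (percentiles 53.8 and 31.4), most of them Trbv segments such as Trbv17, which was covered on both days. Immunoglobulin V segments had an island in 4 and 14 of 225 members (percentiles 20.7 and 63.4). On day 3 these placements moved with the reference: with 100 length bins, added after seeing the data, they were 79.3 for the T cell receptor and 96.1 for the immunoglobulin segments, and with shifted islands 18.1 and 23.3. Klra and Klrb receptor genes had one in 2 of 18 members on each day (percentiles 26.0 and 11.4), with Klra17 covered over 4.67 and 15.9 kb. MHC H2 genes had one in 1 of 38 on each day (percentiles 18.2 and 9.20), H2-Eb2 on day 0 and H2-M3 on day 3. Major urinary protein genes had one in 0 and 1 of 22 (percentiles 7.85 and 19.4), defensin genes in 3 and 2 of 70 (53.2 and 9.22), keratin-associated protein genes in 1 and 3 of 56 (38.5 and 49.0) and interferon alpha genes in 1 and 0 of 13 (83.0 and 23.1). Reads that map to several near-identical copies can be lost or split in such families, and how they were treated is not given in the sources used here.

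Chromosome X held 1 and 3 islands where the density of autosomal islands would give 1386 and 3298. The 4 islands listed there argue against its removal from the processing. Read density varied little between islands: after halving their reads, only 0.035% of autosomal islands on day 0 and 0.063% on day 3 still reached the lowest density of their 1 kb length class. The calculation used no reads from X and would give the same shares if the mark were absent there. It therefore cannot decide the cause. It shows only that a single X per cell, as in male mice, could leave an equally marked X below the calling threshold. The sex of the mice is not stated in the labels, the 2 islands listed on Y on each day (1578 reads on day 0 and 1216 on day 3) were not checked for reads shared with other chromosomes, and a threshold set against input would be less affected, so a lower level of the mark on X stays open as an untested explanation.

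The day 3 list was longer, yet did not contain the day 0 list. A deeper day 3 library that finds the day 0 regions and more would cover most day 0 islands, but 33.6% of them overlapped a day 3 island. That reasoning holds only if day 0 islands are regions that can be found again. Islands near the calling threshold could fail to recur in a deeper library too, so the share cannot decide on depth. The share of 33.6% was 11.6 percentage points above the highest of 1000 shifts within 50 to 500 kb. This argues against placement at any position of a neighbourhood alike. The shifts did not leave out sequence where reads cannot be placed. They therefore cannot tell recurrence of the mark from islands of both lists being confined to the same readable sequence. Autosomal day 0 islands were split into 5 groups by their read density among islands of their length class. The share recurring was 27.1% in the least dense group and 40.1% in the densest, a difference of 13.0 percentage points. A candidate explanation is that many day 0 islands lie near the calling threshold and fail to recur for that reason, although 59.9% of the densest group did not recur either; redistribution of the mark during activation stays open and was not tested.

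The excess on day 3 was regional. Relative to the mean of each list, the difference between days in adjacent 1 Mb windows correlated with r = 0.397 across windows, against at most 0.083 when windows were shuffled within chromosomes, which argues against differences that are independent from window to window. The relative difference was lower where gene bodies took up more of the window (Spearman's rho = -0.37 across windows). Coverage correlated with gene body share at rho = 0.263 on day 0 and -0.096 on day 3, and with gene count at 0.192 and -0.267. Gene bodies were covered more than the rest of the autosomes on day 3 too (9.51% against 7.11%, with no correction for sequence where reads cannot be placed). A difference between the libraries in fragmentation or base composition that follows gene density may give this pattern, and so may a shift of the mark to gene-poor sequence after activation; with 1 library per day, the library and the day are confounded.

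Per the labels' protocols, around 100000000 reads were made per sample. Spread evenly over 2722 Mb, they would give 36.7 reads per kb, and the median densities inside islands were 34.1 on day 0 and 52.9 on day 3. At that depth the median day 0 island was no denser than an even spread. The share of reads that was mapped and kept is not given in the sources used here. Enrichment of the islands over background can therefore not be judged from these counts.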
